A study of Mus musculus with 10 samples.

How the data were processed

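Messenger RNA from corneal endothelial peelings of Slc4a11-/- (KO) and Slc4a11+/+ (WT) mice was measured in 10 libraries, 5 per genotype. Per the labels' protocols, 6 peelings from 3 animals were pooled for each sample, RNA was isolated with a column kit for small inputs, samples with an RNA integrity number over 7 were kept, and libraries were made from 100 ng of total RNA with a stranded kit that selects polyadenylated RNA and 12 PCR cycles, then sequenced in paired-end mode on a NextSeq 500 with a 75-cycle module. The deposited table holds raw read counts per gene and library, made by the authors; its values are whole numbers with a different total in each library. The submitters' processing notes name Trim Galore 0.6.4, cutadapt 2.4, HISAT2 2.1.0, featureCounts and Subread 1.6.4, and the genome GRCm38.p6. The strand setting of the counting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. A polyadenylated RNA protocol measures transcripts that lack a tail, such as most histone messages, less completely.

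Gene identifiers were matched to the GENCODE vM21 annotation of GRCm38, and all 55450 were found; symbols and coordinates come from it. Samples were grouped by the genotype in their labels. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr on the 2 genotype groups (minimum count 10, minimum total 15), libraries were scaled by TMM, and the quasi-likelihood F test compared KO with WT without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 17729 genes tested, and every adjusted p of a single gene is from this test unless another is named. Standard errors of log2 fold changes come from the same model, and CPM values come from the cpm function of edgeR with the TMM-scaled library sizes. Total counts ranged from 36026193 to 51008996 per library, tested genes held 99.9% of them in each, and the common biological coefficient of variation was 16.3%. At this depth a gene at 5 CPM has enough counts for counting error to be small, so the spread between pools sets the precision of all but the rarest transcripts. Reads without molecular identifiers are not independent molecules, so counting intervals would cover counting error only and none are given.

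Gene lists for pathways and for the cell types that a peeled corneal endothelium could hold were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of 918 entries in 37 lists, 917 were found in the table. Lists with at least 5 tested genes (36 lists) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list, and fry, whose directional p does not compare a list with other genes, were run beside it. The mean log2 CPM of each list was compared by a two-sided exact permutation test over all 252 assignments of the libraries, where the smallest p possible is 0.00794 before adjustment over the lists. Counts of list members called were also made adjusted over the list alone. The named genes were Slc4a11; the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM and no overlap between WT and KO libraries, without predicted genes; for each list the 2 called members with the smallest p in each direction; and for a list with no called member its 2 most abundant members. Other members of lists, given where a group of 5 or fewer is listed or as an example, were named after their values were seen, and some genes of the lists and of this rule were analysed but are not reported here. Genes within 10 Mb of Slc4a11 were compared with the rest by Fisher's exact test.

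The alternatives were edgeR with the size factors of DESeq2, with upper quartile factors and with total counts. Others were DESeq2 1.42.0, limma-voom, the robust edgeR fit, no filter on low counts, and a filter of at least 1 CPM in at least 5 libraries. Further ones were the replicate number as a block, and the mean log2 CPM over all keratocyte, epithelial and pigment markers pooled as 1 covariate (the 3-marker covariate). That covariate does not adjust for the 3 marker lists separately. The rest were each library left out in turn, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and windows of 5 and 20 Mb around Slc4a11. A fit with KO 3 and KO 4 as the only KO libraries, and fits with the epithelial or the keratocyte markers alone as covariate, were added after the data had been seen, because epithelial transcripts stood apart in KO 1, KO 2 and KO 5. A fit with the CPM of the Y-linked gene Ddx3y as covariate, for the sex makeup of the pools, was also added after the data had been seen. No 2 libraries of a group matched to within counting noise (chi-square per degree of freedom 14.7 to 87.5), so none was treated as a repeat of another, and each was taken as 1 replicate. The labels do not state whether the 5 pools of a genotype come from different animals.

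The tests were checked on counts simulated from the means and library sizes of the WT and KO libraries for the 17729 genes, with 200 genes changed. The edgeR test recovered 64.2% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 10 false calls (5.78% of its calls). On the same counts limma-voom made 8 false calls (4.68%) and DESeq2 31 (15.4%). Each gene was drawn independently, whereas in the real libraries sets of genes such as the epithelial transcripts vary together. These rates need not hold there.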

Results

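RNA was sequenced from peelings of corneal endothelium, the single cell layer at the back of the cornea that pumps fluid out of the stroma. The mice were C57BL/6, aged 12 weeks, with both copies of Slc4a11 deleted (Slc4a11-/-, KO) or intact (Slc4a11+/+, WT). Slc4a11 encodes a membrane transport protein of the corneal endothelium, and mutations of the human gene cause congenital hereditary endothelial dystrophy. There were 5 libraries per genotype, named here by genotype and number. Per the labels, each sample pooled the peelings of 6 eyes from 3 animals, so the spread between libraries is a spread between pools. Total counts per library ranged from 36026193 in KO 4 to 51008996 in WT 5. Of 55450 genes in the table, 31603 had at least 1 count and 17729 had enough counts to be tested. A2m, which encodes the protease inhibitor alpha-2-macroglobulin, was the most abundant gene in 9 libraries, with 2.68% to 3.64% of the counts. Dcn, a collagen-binding proteoglycan of the stroma, was the most abundant in KO 5. The first principal component held 47.3% of the variance of log2 CPM, where CPM is the count scaled to library size. It did not separate the genotypes, since KO 3 (-25.2) lay within the WT range of -39.6 to -18.5. KO 4 was at 10.5. Highest were KO 1, KO 2 and KO 5 (46.8, 29.9 and 64.8), the libraries with the most epithelial transcripts (below).

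Slc4a11 transcripts were nearly lost in the KO libraries. Slc4a11 (ENSMUSG00000074796.10) is a protein-coding gene on the minus strand of chromosome 2, from 130684113 to 130697519 in GRCm38. It stood at 3791 ± 362 CPM in WT and 95.4 ± 16.2 CPM in KO (SD, n = 5 each), which left 2.52% of the WT level. The KO libraries ranged from 70.1 to 114 CPM and the WT libraries from 3489 to 4357 CPM, so every library had the level its label calls for. The log2 fold change was -5.31 (SE 0.14), a 39.7-fold reduction with the smallest p of all genes tested (edgeR adjusted p = 9.5e-10). Between 2959 and 4787 counts remained in each KO library, and which exons they came from cannot be read from counts per gene.

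**Figure D1:**
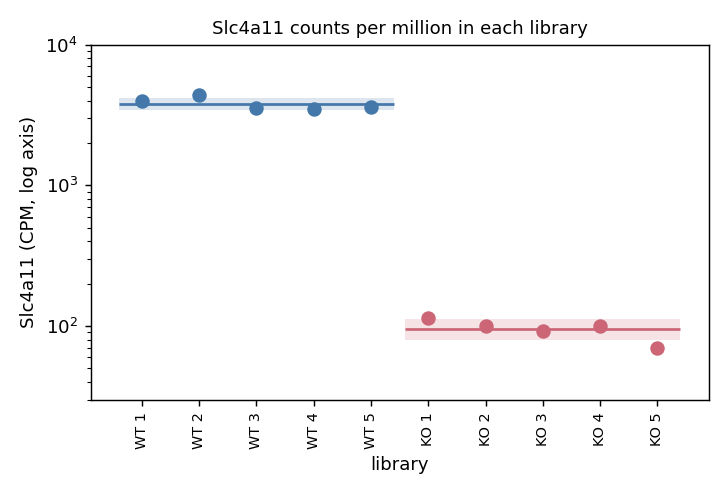
Slc4a11 in each of the 5 WT and 5 KO libraries, in CPM on a log axis; lines are group means and shaded bands 1 SD to each side. The KO libraries lie between 70.1 and 114 CPM and the WT libraries between 3489 and 4357 CPM.

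The comparison of KO with WT asked which genes differ in expression in corneal endothelial peelings when Slc4a11 is missing. The peelings also held abundant transcripts of stromal keratocytes, such as Kera at 8087 CPM in WT. The cell type in which a gene changed therefore cannot be told from these libraries. Sv2c, a synaptic vesicle glycoprotein, rose from 7.78 ± 1.18 to 35.5 ± 8.49 CPM (SD, n = 5; log2 fold change 2.19, SE 0.17). Vwde, named for its von Willebrand factor D and EGF domains, fell from 126 ± 21.1 to 10.5 ± 2.18 CPM (log2 fold change -3.58, SE 0.16). Vldlr, the very low density lipoprotein receptor, fell from 14.5 ± 3.64 to 1.84 ± 0.236 CPM (log2 fold change -2.97, SE 0.18). Ret, a receptor tyrosine kinase for ligands of the GDNF family, rose 3.20-fold, and Tnfrsf12a, the receptor of the cytokine TWEAK, rose 3.32-fold. Idi1, an enzyme of isoprenoid synthesis, rose 2.95-fold. The edgeR adjusted p was 1.3e-05 for Sv2c, 7.6e-05 for Ret, 3.9e-04 for Tnfrsf12a and 8.3e-06 for Idi1.

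Frem3, an extracellular matrix protein of the basement membrane zone, was among the more abundant genes that fell, from 826 ± 20.5 to 144 ± 35.2 CPM (SD, n = 5; log2 fold change -2.52, SE 0.15). The complement receptor Cr2 fell 5.26-fold and the vesicular monoamine transporter Slc18a2 4.64-fold. The neurotrophin receptor Ntrk3 fell 3.67-fold and the prostaglandin E receptor Ptger3 3.40-fold. Slc16a3, the lactate exporter MCT4, fell from 82.0 ± 10.02 to 20.7 ± 4.16 CPM, and Ndufa4l2, a hypoxia-induced mitochondrial protein, from 61.7 ± 16.3 to 16.4 ± 1.63 CPM. WT and KO libraries did not overlap for any of these genes, nor for Vwde and Vldlr, and the edgeR adjusted p of all of them lay between that of Vwde (2.1e-07) and that of Cr2 (1.9e-05).

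Other named genes with large rises were uneven between KO libraries or uncertain in identity. Perp, a desmosome protein that is also an epithelial marker, rose from 8.91 ± 1.83 to 56.0 ± 51.3 CPM (SD, n = 5; edgeR adjusted p = 0.0082). The water and glycerol channel Aqp3 rose from 13.01 ± 2.23 to 45.4 ± 38.1 CPM (edgeR adjusted p = 0.025). The heat shock gene Hspa1b, which has a near-identical copy in Hspa1a, rose from 2.34 ± 0.394 to 8.96 ± 6.04 CPM (edgeR adjusted p = 0.0092). When KO 3 and KO 4 were the only KO libraries, the log2 fold change was 0.83 for Perp against 2.66 (SE 0.56) with all 5. The calls of Aqp3 (0.31, edgeR adjusted p = 0.29) and Hspa1b (0.64, edgeR adjusted p = 0.089) were then lost, and Aqp3 was also not called without WT 3, WT 5 or KO 1 (1.62 to 1.74). Tceanc2, a homolog of transcription elongation factors, rose from 2.90 ± 0.555 to 13.4 ± 2.55 CPM (edgeR adjusted p = 8.5e-06) but overlaps Tmem59, at 1124 CPM, on the opposite strand. The strand setting of the counting is not given in the sources used here, so 16 of the 108 named genes, which overlap a tested gene on the opposite strand, are uncertain. They are Tceanc2, Ndufa4l2 with Shmt2, Ntrk3, Slc4a2, Ndufa3, G6pdx, Slc7a5, Tagln, Nfkb2, Ciart, Jun, Grip1, Plvap, Bfsp2 and Opn1mw.

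**Figure D2:**
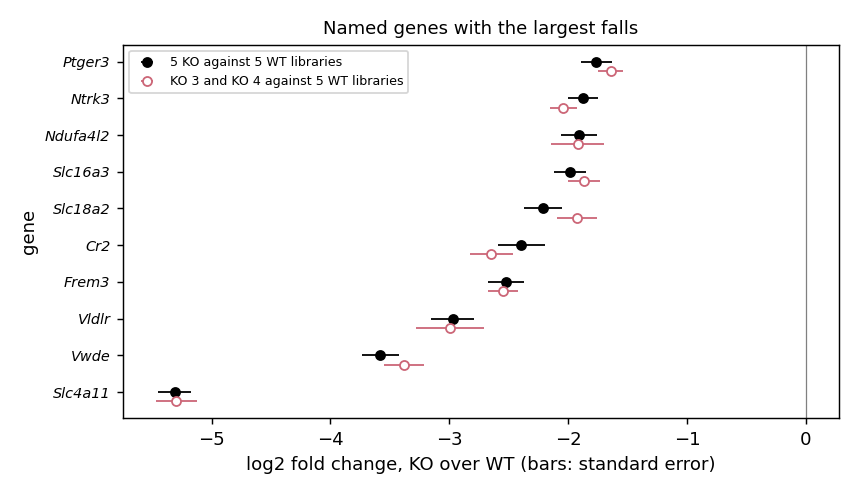
Log2 fold change of KO over WT for Slc4a11 and the other 9 named genes with the largest falls, with bars of 1 standard error; filled points use 5 KO and 5 WT libraries, open points KO 3 and KO 4 against 5 WT libraries. Vwde is at -3.58 in the larger and -3.38 in the smaller set, and Slc18a2 at -2.21 and -1.92.

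In all, 1346 genes rose and 1370 fell in KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which is 15.3% of the genes tested. Of these, 382 rose and 213 fell by at least 1 on the log2 scale, and the median size of a called change was 0.49. WT and KO libraries did not overlap for 2135 genes (12.0%), where chance gives 0.794%. When libraries were scaled to total counts alone, 1555 genes rose and 1054 fell. The share of rises among the calls was then 59.6%, against 49.6% with the TMM factors used here. The median log2 fold change of all tested genes was 0.00 with TMM and 0.03 with total counts. Epithelial marker transcripts were far more abundant in KO 1, KO 2 and KO 5 than in any WT library, slightly more abundant in KO 4 and within the WT range in KO 3. The fit with KO 3 and KO 4 as the only KO libraries called 527 rises and 578 falls; 436 and 531 of them were among the 1346 and 1370, and 0 genes called in both fits changed direction. The number of rises was 836 without WT 3, 850 without WT 5 and 895 without KO 1. With the pooled mean of keratocyte, epithelial and pigment markers as a single covariate, 578 genes rose and 686 fell.

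Genes of cholesterol synthesis rose together in KO. Of 23 tested members, 22 rose, none fell and 1 did not pass, and 23 rose when adjusted over the list alone. The median log2 fold change was 0.84. Insig1, a sterol-sensing regulator of the pathway, rose from 42.4 ± 4.11 to 112 ± 13.8 CPM (SD, n = 5; log2 fold change 1.41, SE 0.09), and Idi1 from 8.74 ± 0.699 to 25.8 ± 4.70 CPM. The member that did not pass was Pmvk at 0.18 (edgeR adjusted p = 0.14). Pmvk was named after its value was seen. The list was higher by camera with a preset correlation of 0.01 (adjusted p = 3.0e-21; adjusted p = 0.30 with an estimated correlation). Its mean log2 CPM was higher in KO by an exact permutation test (adjusted p = 0.0245, n = 5 each). In the fit with KO 3 and KO 4, the KO libraries with the fewest epithelial transcripts, the median was 0.88 and 17 members rose.

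Genes of glycolysis and targets of the hypoxia-inducible factor (HIF) fell together. In the glycolysis list 16 of 22 tested members fell, none rose and 6 did not pass, and 18 fell when adjusted over the list alone. Its median was -0.62. Pfkfb3, which makes the activator of phosphofructokinase, fell from 49.2 ± 4.17 to 19.5 ± 2.09 CPM (SD, n = 5; log2 fold change -1.34, SE 0.08). Ldha, which converts pyruvate to lactate and was named after its value was seen, fell from 679 ± 124 to 353 ± 28.6 CPM. In the HIF list 17 of 22 fell, none rose and 5 did not pass, and 18 fell when adjusted over the list alone. Its median was -0.64, and Bnip3, a mitophagy receptor, fell from 106 ± 13.6 to 36.8 ± 4.96 CPM (log2 fold change -1.53, SE 0.11). The HIF members that did not pass were Mxi1, Ndrg1, Egln3, Adm and Pfkfb4. The 2 lists share 4 genes. Both were lower by camera (adjusted p = 5.0e-14 for each), with adjusted p = 0.30 for glycolysis and adjusted p = 0.052 for HIF targets with an estimated correlation. Both had lower mean log2 CPM by the exact permutation test (adjusted p = 0.0245). KO 3 and KO 4, the KO libraries with the lowest epithelial levels, alone gave medians of -0.57 and -0.67, with 14 and 16 members lower and, in the HIF list, 1 higher.

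**Figure D3:**
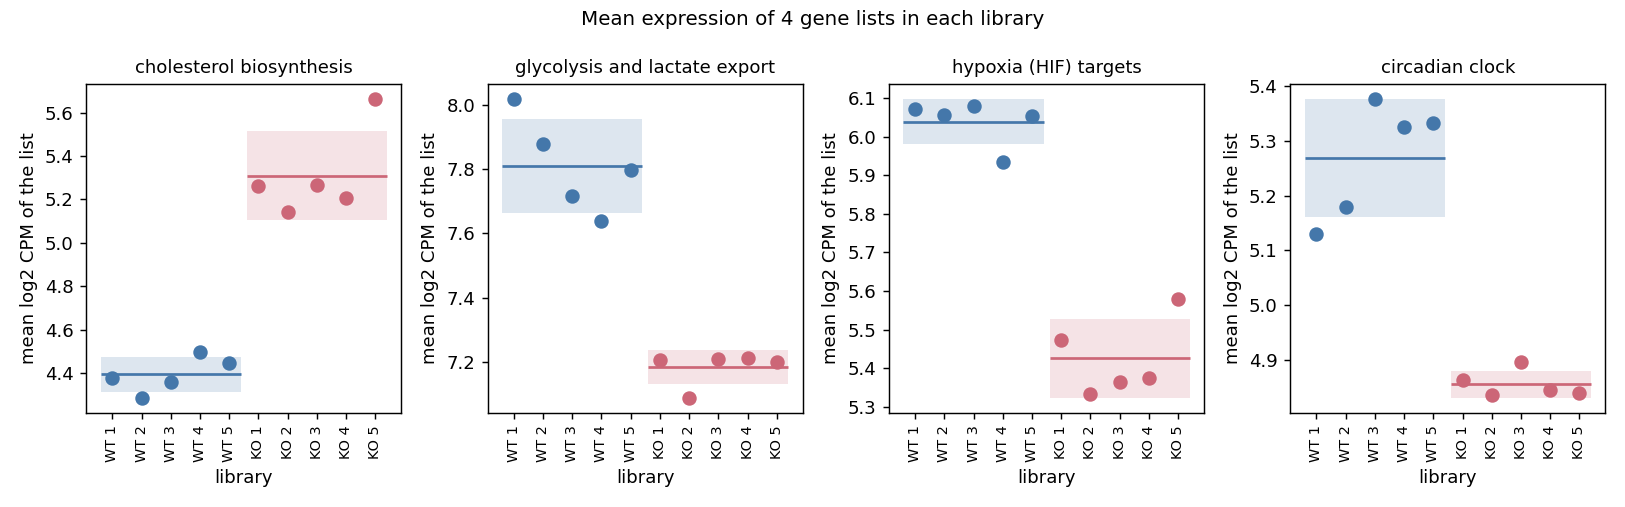
Mean log2 CPM of the cholesterol synthesis, glycolysis, HIF target and clock lists in each of the 5 WT and 5 KO libraries, each panel with its own vertical scale; lines are group means and shaded bands 1 SD to each side. WT and KO libraries do not overlap in any of the 4 lists.

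Circadian clock genes changed in both directions, with 13 of 19 tested members lower, 5 higher and 1 not passed. These counts were the same when adjusted over the list alone. Ciart, a repressor of the clock, fell from 6.20 ± 1.25 to 1.01 ± 0.254 CPM (SD, n = 5; log2 fold change -2.61, SE 0.19). Nr1d2, a nuclear receptor that represses Arntl, fell by 0.86 on the log2 scale. Dbp, a clock output factor named after its value was seen, fell from 170 ± 12.4 to 79.5 ± 12.8 CPM. Nfil3, a repressor of Dbp targets, rose by 1.12 (SE 0.16). Npas2 rose by 0.76, Arntl by 0.58 and Cry1 by 0.40, and Clock itself was at 0.05 (edgeR adjusted p = 0.76). The list was lower by camera (adjusted p = 3.1e-04; adjusted p = 0.30 with an estimated correlation). Its mean log2 CPM was lower by the exact permutation test (adjusted p = 0.0245). The fit with KO 3 and KO 4 had 10 members lower, 2 higher and a median of -0.59, against -0.65 with all libraries.

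Ion and water transport genes of the corneal endothelium changed in part. Of 29 tested members 6 fell, 3 rose and 20 did not pass, and 8 fell and 3 rose when adjusted over the list alone. Besides Slc16a3, Atp1b2, a beta subunit of the sodium pump, fell from 35.7 ± 2.74 to 14.4 ± 2.31 CPM (SD, n = 5; log2 fold change -1.32, SE 0.10). The 3 that rose were the carbonic anhydrase Car2 by 0.72 (SE 0.17), the anion exchanger Slc4a2 by 0.27 (SE 0.06) and the pump subunit Atp1b3 by 0.30 (SE 0.08). The water channel Aqp1 was at 0.09 (edgeR adjusted p = 0.48). The bicarbonate cotransporter Slc4a4 was at -0.31 (edgeR adjusted p = 0.070). The list was not called by camera (median -0.04, adjusted p = 0.053, and adjusted p = 0.53 with an estimated correlation). Its mean log2 CPM was lower by the exact permutation test (adjusted p = 0.0245). Camera called it without KO 1 (adjusted p = 0.0269) or KO 4 (adjusted p = 0.0348), with total counts (adjusted p = 0.0405), with upper quartile factors (adjusted p = 0.0453) and with the CPM filter (adjusted p = 0.0488), as did fry (adjusted p = 0.0101). The fit with KO 3 and KO 4 had 5 members lower and none higher, but camera did not call the list there (adjusted p = 0.154).

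Markers of corneal endothelial cells share 6 genes with the transport list, and 3 of 17 fell, none rose and 14 did not pass. Adjusted over the list alone, 3 fell. They were Slc16a3, Grip1, a scaffold protein of synapses that fell 2.11-fold, and Atp1b1, which fell by 0.32 on the log2 scale. The list had a median of -0.11 and was lower by camera (adjusted p = 0.031; adjusted p = 0.67 with an estimated correlation). This call was lost without WT 5 (adjusted p = 0.0634) and without KO 5 (adjusted p = 0.186). It was also lost with KO 3 and KO 4 as the only KO libraries (adjusted p = 0.433). Col8a2, a collagen of Descemet membrane, did not pass, with 7374 ± 432 CPM in WT and 7619 ± 663 CPM in KO (SD, n = 5; edgeR adjusted p = 0.72).

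Junction and adhesion genes were higher as a list. Of 32 tested, 14 rose, 2 fell and 16 did not pass, and 14 rose and 3 fell when adjusted over the list alone. F11r, the junctional adhesion molecule JAM-A, rose from 47.8 ± 3.18 to 74.8 ± 9.65 CPM (SD, n = 5; log2 fold change 0.65, SE 0.08) and Nectin1 by 0.90 (SE 0.16). The integrins Itgb1 and Itga6 fell by 0.27 and 0.21 on the log2 scale, and Itga6 was not called without WT 4, WT 5, KO 2, KO 4 or KO 5 (-0.22 to -0.17). The list was higher by camera (median 0.22, adjusted p = 8.5e-04; adjusted p = 0.49 with an estimated correlation). Some members that rose are abundant in epithelium. The epithelial cadherin Cdh1 was at 4.30 (SE 1.00) with all libraries and at 1.12 (edgeR adjusted p = 0.40) with KO 3 and KO 4 only. F11r and Nectin1 were at 0.54 and 0.64 in that fit, where 9 members rose and none fell.

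The stress lists were mixed. In the integrated stress response list 6 of 21 rose, 4 fell and 11 did not pass, and 8 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.19). The amino acid transporter subunits Slc7a5 and Slc3a2 rose from 111 ± 12.4 to 326 ± 115 CPM and from 367 ± 23.5 to 611 ± 119 CPM (SD, n = 5). Vldlr and Shmt2, a mitochondrial serine enzyme, fell 7.85-fold and 1.52-fold. Among NRF2 targets 6 of 27 rose, 1 fell and 20 did not pass, and 7 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.19). The heme oxygenase Hmox1 rose from 6.22 ± 0.591 to 13.7 ± 1.73 CPM, and the epoxide hydrolase Ephx1 fell 1.27-fold.

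Immediate early genes were higher as a list (median 0.40, camera adjusted p = 0.0018; adjusted p = 0.49 with an estimated correlation). Of 23 tested, 6 rose, none fell and 17 did not pass, and 7 rose when adjusted over the list alone. Jun rose 2.01-fold and Btg2 1.76-fold. The list call was lost with KO 3 and KO 4 only (median 0.16, camera adjusted p = 0.0644), where 6 members rose. The p53 target and senescence list was not called (camera adjusted p = 0.075), with 5 of 21 higher, 2 lower and 14 not passed, and with 8 higher and 2 lower adjusted over the list alone. Its mean log2 CPM was higher by the exact permutation test (adjusted p = 0.0245), and it was called by fry (adjusted p = 2.1e-04), with DESeq2 (camera adjusted p = 0.0402) and without a filter on low counts (camera adjusted p = 0.0410). Bbc3, a pro-apoptotic gene, rose 2.03-fold to 1.22 ± 0.151 CPM (SD, n = 5). In the unfolded protein response list 4 of 26 rose, none fell and 22 did not pass, and 4 rose and 1 fell when adjusted over the list alone. Sdf2l1, a protein of the endoplasmic reticulum, rose 1.39-fold. The list was higher by camera (median 0.05, adjusted p = 0.031; adjusted p = 0.67 with an estimated correlation). Its call was lost without WT 1, WT 2, WT 3, KO 1, KO 2 or KO 4 (camera adjusted p of 0.0502 to 0.0889) and with KO 3 and KO 4 only (camera adjusted p = 0.365).

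Nuclear-encoded oxidative phosphorylation genes were slightly higher as a list (median 0.08, camera adjusted p = 0.0018; adjusted p = 0.77 with an estimated correlation). Of 75 tested, 5 rose, none fell and 70 did not pass, and 0 passed when adjusted over the list alone. Ndufa3 and Ndufc2, subunits of complex I, rose by 0.30 (SE 0.07) and 0.24 (SE 0.06), and the other 3 were Ndufa4, Uqcrq and Cox6a1. Ndufc2 was not called without WT 2, WT 3 or WT 5 (0.21 to 0.24). The list call was lost without KO 5 (adjusted p = 0.0812) and with KO 3 and KO 4 only (adjusted p = 0.424). Transcripts of the mitochondrial genome were lower as a list (median -0.72, camera adjusted p = 0.019; adjusted p = 0.67 with an estimated correlation). Of 13 tested, 1 fell, mt-Co3, from 2273 ± 262 to 1381 ± 431 CPM (SD, n = 5), and 12 did not pass. Adjusted over the list alone, 1 fell. That list call was lost without WT 2, WT 3 or KO 3 (adjusted p of 0.0759 to 0.0860). With KO 3 and KO 4 only it was kept, with a median of -1.10 (camera adjusted p = 4.1e-04) and 3 members lower.

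Antioxidant enzymes and metallothioneins were higher as a list (median 0.10, camera adjusted p = 0.019; adjusted p = 0.67 with an estimated correlation). The peroxidase Gpx1 rose from 159 ± 12.7 to 232 ± 17.1 CPM (SD, n = 5), and 23 of 24 did not pass. Adjusted over the list alone, 1 rose. This list call was lost without WT 3 (adjusted p = 0.0826), without KO 5 (adjusted p = 0.130) and with KO 3 and KO 4 only (adjusted p = 0.154). In the glutamine and citric acid cycle list 3 of 29 fell, none rose and 26 did not pass, and 6 fell when adjusted over the list alone (camera adjusted p = 0.76). Among them were the isocitrate dehydrogenase Idh2 and the glutamine transporter Slc1a5, which was not called without WT 4, WT 5 or KO 1 (-0.20 in each). In the fatty acid oxidation list 3 of 25 rose, 2 fell and 20 did not pass (camera adjusted p = 0.76), with the same counts adjusted over the list alone. Angptl4, an inhibitor of lipoprotein lipase, fell 2.02-fold. The median of this list was 0.01 and its mean -0.01.

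Interferon response genes were lower as a list (median -0.16, camera adjusted p = 0.0036; adjusted p = 0.53 with an estimated correlation). Of 29 tested, 5 fell, none rose and 24 did not pass, and 9 fell when adjusted over the list alone. Ifit3 fell from 61.5 ± 9.45 to 37.2 ± 6.17 CPM (SD, n = 5) and Ifi44 fell 1.82-fold. Neither gene passed with KO 3 and KO 4 only (edgeR adjusted p = 0.052 and 0.15), where 1 member fell. Their log2 fold changes in that smaller fit were -0.71 and -0.53, against -0.73 and -0.86 with all libraries. The list median stayed at -0.16, and camera still called the list there (adjusted p = 0.0231). In the list of inflammatory cytokines and NF-kB targets 2 of 21 rose, 5 fell and 14 did not pass, and 3 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.93). The adhesion molecules Vcam1 and Icam1 fell from 180 ± 41.5 to 107 ± 14.7 CPM and from 71.8 ± 13.3 to 46.5 ± 5.76 CPM.

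In the list of basement membrane and Descemet membrane matrix 4 of 31 rose, 5 fell and 22 did not pass, and 5 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.93). Its median was -0.00 and its mean 0.17. Thbs1, the matrix glycoprotein thrombospondin 1, rose from 2266 ± 297 to 3911 ± 981 CPM (SD, n = 5), and the laminin Lamb1 fell by 0.74 on the log2 scale (SE 0.09). In the TGF-beta and myofibroblast list 4 of 28 rose, 5 fell and 19 did not pass, and 6 rose and 9 fell when adjusted over the list alone (camera adjusted p = 0.76). Inhba, an activin subunit, rose 2.82-fold to 0.778 ± 0.112 CPM.

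Lysosome genes were not called as a list (camera adjusted p = 0.93), with 7 of 57 lower, 2 higher and 48 not passed. The counts were the same adjusted over the list alone. The membrane protein Scarb2 and the acid lipase Lipa fell 1.33-fold and 1.32-fold. Autophagy genes were not called either (camera adjusted p = 0.93), with 8 of 41 lower, 2 higher and 31 not passed, and with 9 lower and 5 higher adjusted over the list alone. Bnip3 was the first of those that fell, and Atg10, a ligase of the conjugation system, fell 1.38-fold. For lysosome and autophagy the median was above 0 (0.02 and 0.06) and the mean below it (-0.01 and -0.06). The mean log2 CPM of the autophagy list was lower by the exact permutation test (adjusted p = 0.0245, n = 5 each).

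None of 42 ribosomal protein genes passed, over all genes or adjusted over the list alone (median 0.06, camera adjusted p = 0.055; adjusted p = 0.95 with an estimated correlation). The most abundant were Rpl4 at 759 ± 59.4 CPM and Rplp0 at 746 ± 114 CPM in WT (SD, n = 5), genes whose pseudogenes can share reads with them. Without WT 1 the list was called (median 0.14, camera adjusted p = 2.9e-05), as it was without KO 1, KO 3 or KO 4, with total counts (0.0210), DESeq2 (0.0235), no filter (0.0224), the replicate block (0.0483) and the keratocyte covariate (0.00559). Rplp0 rose without WT 1 (0.31, edgeR adjusted p = 0.034). Cell proliferation genes were higher as a list (median 0.47, camera adjusted p = 0.0018; adjusted p = 0.54 with an estimated correlation). Of 25 tested, 4 rose, none fell and 21 did not pass, and 7 rose and 1 fell when adjusted over the list alone. They were the replication genes Mcm5 and Rrm2 and the mitotic genes Cdk1 and Birc5. Their levels were low, 5.51 ± 0.459 CPM for Mcm5 and 0.730 ± 0.534 CPM for Rrm2 in KO. Rrm2 was not called without WT 1, WT 3, WT 5 or KO 1 (1.56 to 1.69), and with KO 3 and KO 4 only the list median was 0.04 (camera adjusted p = 0.766) and none rose.

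In all, 11 of the 36 lists tested were higher and 8 lower by camera with the preset correlation. When the correlation was estimated for each list, limma camera called 0 lists, and limma fry called 5 higher and 5 lower. The lists fry called higher were cholesterol synthesis, junctions, immediate early genes, nerve and Schwann cells, and p53 targets; those it called lower were glycolysis, HIF targets, clock, red blood cells and transport. By the exact permutation test of mean log2 CPM, 10 of the 19 lists passed: cholesterol synthesis, glycolysis, HIF targets, clock, junctions, interferon response, immediate early genes, corneal endothelial cells, and nerve and Schwann cells (adjusted p = 0.0245 each), and vessels (adjusted p = 0.0452). The other 9 did not pass it (exact permutation adjusted p of 0.0734 to 0.314). With the epithelial or the 3-marker covariate camera no longer called the lists of oxidative phosphorylation, antioxidant enzymes, unfolded protein response, proliferation, corneal endothelial cells, epithelium, macrophages, red blood cells and retina (adjusted p of 0.0629 for retina or more). At an unadjusted p under 0.05, HIF targets (p = 0.0014), cholesterol synthesis (p = 0.0171), glycolysis (p = 0.0317) and the clock (p = 0.0330) passed camera with the estimated correlation. Cholesterol synthesis, glycolysis, HIF targets, clock, junctions, interferon response, and nerve and Schwann cells kept their camera call with the preset correlation in each fit that left out 1 library, with KO 3 and KO 4 only and with the marker covariates.

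Transcripts of corneal and conjunctival epithelium, the surface layer on the opposite side of the cornea, were higher in some KO libraries. Of 21 tested markers 15 rose, none fell and 6 did not pass, and 20 rose when adjusted over the list alone. The median log2 fold change was 3.85. The list was higher by camera (adjusted p = 9.3e-05; adjusted p = 0.67 with an estimated correlation). The difference of mean log2 CPM did not pass an exact permutation test (adjusted p = 0.153, n = 5 each). The mean log2 CPM of the list was -0.57 to 2.20 in WT, and 5.59 in KO 1, 3.76 in KO 2, -0.49 in KO 3, 2.51 in KO 4 and 5.91 in KO 5. Krt12, the keratin of corneal epithelium, was at 540 CPM in KO 1 and 1693 CPM in KO 5 but at 2.87 CPM in KO 3, against 4.66 to 67.9 CPM in WT. Krt19 rose from 0.315 ± 0.217 to 7.73 ± 8.36 CPM (SD, n = 5; edgeR adjusted p = 0.013). With KO 3 and KO 4 as the only KO libraries, the list median was 0.39 (camera adjusted p = 0.840) and 1 marker, Perp, rose.

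Keratocytes, the cells of the corneal stroma, gave the most abundant markers of the cell type lists. Of 19 tested, 3 fell, none rose and 16 did not pass (median -0.08, camera adjusted p = 0.35), with the same counts adjusted over the list alone. Kera, the proteoglycan keratocan, was at 8087 ± 1679 CPM in WT and 5817 ± 468 CPM in KO (SD, n = 5; edgeR adjusted p = 0.030). Col6a3, a collagen VI chain, fell 1.47-fold and Ptgds, a prostaglandin D synthase, by 0.83 on the log2 scale. Dcn did not pass (log2 fold change -0.10, edgeR adjusted p = 0.54). Kera was not called without WT 1, WT 4, WT 5, KO 1, KO 3 or KO 4 (-0.49 to -0.39), and the list was called with KO 3 and KO 4 only (median -0.17, camera adjusted p = 0.0471).

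**Figure D4:**
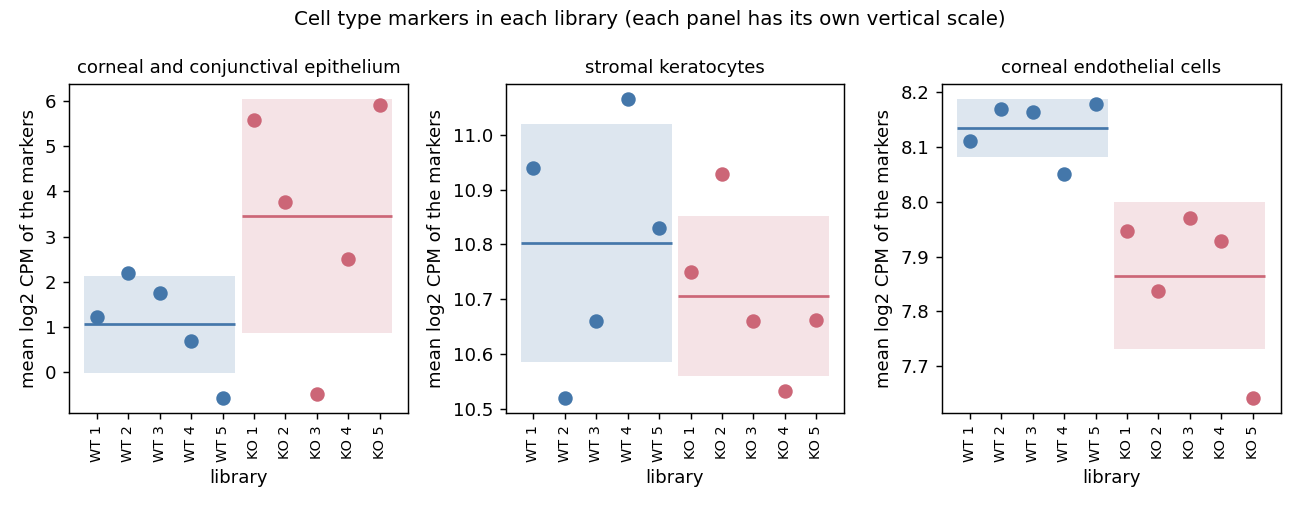
Mean log2 CPM of the epithelial, keratocyte and corneal endothelial markers in each of the 5 WT and 5 KO libraries, each panel with its own vertical scale; lines are group means and shaded bands 1 SD to each side. The epithelial markers reach 5.59 in KO 1 and 5.91 in KO 5, above the highest WT library at 2.20, while KO 3 at -0.49 lies within the WT range.

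Markers of nerve and Schwann cells were higher as a list (median 0.49, camera adjusted p = 0.0018; adjusted p = 0.53 with an estimated correlation). Of 11 tested, 6 rose, 1 fell and 4 did not pass, and the counts were the same adjusted over the list alone. With KO 3 and KO 4 only, the list stayed called (camera adjusted p = 0.0138), with a smaller median of 0.29 and 2 members higher. The adhesion molecule Ncam1 fell by 0.24 on the log2 scale and was not called without WT 2, WT 3, WT 4, WT 5 or KO 1 (-0.24 to -0.21).

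Markers of macrophages and dendritic cells were higher (median 0.26, camera adjusted p = 0.011; adjusted p = 0.68 with an estimated correlation). Of 22 tested, 4 rose, none fell and 18 did not pass, and 6 rose when adjusted over the list alone. The 4 were the scavenger receptor Cd163 and the MHC class II genes H2-Ab1, H2-Aa and H2-Eb1, and H2-Ab1 was not called without WT 2 or WT 3 (0.59 to 0.64). The list call was lost without WT 3, KO 2 or KO 5 (adjusted p of 0.0702 to 0.120) and with KO 3 and KO 4 only (adjusted p = 0.766). Markers of blood and lymph vessels were higher (median 1.03, camera adjusted p = 0.019; adjusted p = 0.53 with an estimated correlation). Of 11 tested, 2 rose, 1 fell and 8 did not pass, and 6 rose and 1 fell when adjusted over the list alone. The 2 that rose, Plvap and Tie1, reached 1.52 ± 0.496 and 0.763 ± 0.440 CPM in KO, whereas Kdr, a receptor of VEGF, fell from 121 ± 17.99 to 84.2 ± 9.07 CPM (SD, n = 5). The list was not called with KO 3 and KO 4 only (camera adjusted p = 0.0548).

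Markers of red blood cells were lower (median -1.67, camera adjusted p = 0.019; adjusted p = 0.53 with an estimated correlation). Of 6 tested, 1 fell, none rose and 5 did not pass, and 5 fell when adjusted over the list alone. The list was not called without WT 1 (camera adjusted p = 0.0593), with the epithelial covariate (camera adjusted p = 0.109) or with the 3-marker covariate (camera adjusted p = 0.117). Retina markers were lower (median -1.38, camera adjusted p = 0.0031; adjusted p = 0.54 with an estimated correlation). Of 11 tested, 2 fell, Rbp3 and Nrl, 1 rose, Opn1mw, and 8 did not pass, and 7 fell and 1 rose when adjusted over the list alone. Levels were low, 1.18 ± 0.479 CPM for Rbp3 in WT (SD, n = 5). Opn1mw was not called without WT 1, WT 2, WT 5, KO 1, KO 2, KO 3 or KO 4 (0.88 to 1.03), and the list was not called with KO 3 and KO 4 only (camera adjusted p = 0.0654).

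Lens markers were not called (median 0.37, camera adjusted p = 0.073). Of 6 tested, 2 rose, Bfsp2 and Cryaa, none fell and 4 did not pass, and 3 rose when adjusted over the list alone. Cryaa was not called without WT 3 or WT 5 (1.41 to 1.43), and the list was called without KO 2 (median 0.84, camera adjusted p = 0.0364) and with KO 3 and KO 4 only (median 1.03, camera adjusted p = 0.00311). It was also called with the CPM filter (camera adjusted p = 0.0498), the 3-marker covariate (0.0357) and the epithelial covariate (0.0429). Of 6 markers of trabecular meshwork and muscle 2 rose, Myoc and Mgp, 1 fell, Myh11, and 3 did not pass (camera adjusted p = 0.93). Adjusted over the list alone, 2 rose and 2 fell; the median was -0.02 and the mean 0.12. Myoc was not called without WT 2, WT 3, KO 2 or KO 4 (0.93 to 1.03), nor Mgp without WT 1, WT 2, WT 3, WT 5, KO 2, KO 4 or KO 5 (0.41 to 0.53). None of 6 pigment cell markers passed, over all genes or adjusted over the list alone (camera adjusted p = 0.40), and Gpnmb was at 141 ± 29.6 CPM in WT and 122 ± 11.8 CPM in KO (SD, n = 5). The list of neutrophils and lymphocytes had 4 tested genes, too few for a list test. Cd4 rose from 0.185 ± 0.0380 to 0.832 ± 0.184 CPM and 3 genes did not pass, with the same counts adjusted over the list alone. None of 5 sex-linked transcripts passed, over all genes or adjusted over the list alone (camera adjusted p = 0.93).

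Genes close to Slc4a11 were compared with genes elsewhere, because a targeted allele can carry flanking DNA of another strain. Of 181 tested genes starting within 10 Mb of Slc4a11 on chromosome 2, 28 were called (15.5%), against 2687 of 17547 elsewhere (15.3%). The odds ratio was 1.01 (95% interval 0.65 to 1.53; two-sided Fisher exact p = 0.918), so calls were not detectably more frequent near the deleted gene.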

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

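The tests chosen only after the result was seen were whether the epithelial markers were higher in every KO library, the list medians with KO 3 and KO 4 only and with the Ddx3y level as covariate, and the interval around the spread of epithelial ratios. The fit with the keratocyte markers alone as covariate was also added after the data had been seen, with the bound for its list medians written before they were computed. Of 100 splits of the 10 libraries into 5 and 5, drawn from the 126 possible, 1 gave as many genes as the 2716 called between KO and WT, the real split itself. The highest count of any other split was 0 with edgeR and 1 with limma-voom, though other splits had up to 4689 genes at an unadjusted p under 0.05, against 5515. This argues against a chance division of the libraries for the count of genes, with a share of 1 in 100, the smallest possible here. Every other split mixes KO and WT libraries, so genes that differ by genotype widen its spread and favour a count of 0. The splits also cannot separate genotype from any other difference that runs with it. For gene lists called by camera with the preset correlation, 5 of the 100 splits gave as many as the real 19, and the highest other split gave 20. The other splits gave a median of 10 lists, although edgeR called 0 genes in each of them. Chance therefore cannot be excluded for the count of lists. Of the 4 other splits that gave as many, 3 exchanged 1 library between the groups and 1 exchanged 2.

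Epithelial transcripts were high in KO 1, KO 2 and KO 5, near the highest WT library in KO 4 and low in KO 3. Of 21 markers, 21, 20, 1, 13 and 21 lay above the highest WT library in KO 1 to KO 5. Induction of these genes by loss of Slc4a11 stays open, since only 1 KO library, KO 3, had a mean log2 CPM within the WT range, and 1 library decides nothing. Epithelial tissue carried over with the peelings in differing amounts may also account for the pattern, and its test could not decide either. Tissue of 1 kind would keep 1 ratio between genes, and the SD of the log2 ratio of KO 5 to KO 1 was 1.19, over the bound of 1 set beforehand, but its 95% interval of 0.912 to 1.72, added once the value was known, holds that bound; Krt4 at 78.7 CPM in KO 1 and 4.90 CPM in KO 5 goes against a single ratio, which tissue of differing makeup (cornea and conjunctiva) would not keep.

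Cholesterol synthesis genes were higher and glycolysis genes and HIF targets lower in each KO library than in each WT library. Carried-over epithelium as the whole cause is argued against by the medians with KO 3 and KO 4 only, 0.88, -0.57 and -0.67, against 0.84, -0.62 and -0.64 with all libraries, while that of the epithelial markers went from 3.85 to 0.39. The medians were 0.87, -0.63 and -0.62 with the keratocyte markers as covariate, and 0.83, -0.63 and -0.64 with the level of the Y-linked gene Ddx3y. Both covariates were much alike in the 2 groups. The keratocyte markers had a mean log2 CPM of 10.8 in WT and 10.7 in KO. Ddx3y ranged from 22.7 to 93.3 CPM in WT and from 17.7 to 78.9 CPM in KO. Such covariates can hardly move the medians. The likeness of the groups, more than the medians, argues against keratocyte share or sex makeup as the whole cause. Lower transcript levels of hypoxia and lactate genes and higher levels of sterol synthesis genes in response to the loss of Slc4a11 stay a hypothesis found and examined on the same data, with none of the 3 lists called with an estimated correlation; restoring Slc4a11 in KO endothelium from animals matched for litter and time of dissection, and measuring these transcripts with lactate and sterol levels, would test it. Differences between the pools that the labels do not give, such as the time of dissection or the litters, were not tested for these lists. A lower share of endothelial cells in the KO peelings was not tested either and stays open. The endothelial markers, which include Slc16a3, had a mean log2 CPM of 8.05 to 8.18 in WT and 7.64 to 7.97 in KO. KO 3 and KO 4 were at 7.97 and 7.93, so the fit with these libraries does not remove that difference.

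Clock genes changed in both directions, and the list median was -0.65. With KO 3 and KO 4 only, the median was -0.59, with 10 members lower and 2 higher. This argues against carried-over epithelium as the whole cause of the falls, and a median over members that go both ways says little about the rises. The median was -0.63 with the Ddx3y level as covariate, which was much alike in the groups and so could hardly move it. The labels give no time of day, and neither a different time of dissection nor a shifted clock in KO corneas was tested, so both stay open.

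Among 296 groups of 5 libraries, for named genes and list scores, 17 had 1 library far from the other 4, where chance gives about 14.8 (1 in 20); 15 of the 17 are given below. Idi1 was at 33.9 CPM in KO 5, against 21.6 to 24.96 CPM in the other KO libraries. Ntrk3 was at 33.3 CPM in KO 2, against 20.5 to 24.2 CPM. Ptger3 was at 3.79 CPM in KO 5, against 6.19 to 6.53 CPM. Ndufc2 was at 63.9 CPM in KO 5, against 55.1 to 57.4 CPM. Kdr was at 99.9 CPM in KO 3, against 77.7 to 83.6 CPM. Gpnmb was at 143 CPM in KO 5, against 115 to 119 CPM. Nrl was at 0.304 CPM in KO 3, against 0.0805 to 0.126 CPM. In WT, Ifit3 was at 44.6 CPM in WT 2 (others 65.1 to 66.1) and Rpl4 at 862 CPM in WT 1 (others 716 to 751).

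The same held for 6 list scores, the mean log2 CPM of a list in a library. KO 5 was high for cholesterol synthesis (5.66, others 5.14 to 5.27), oxidative phosphorylation (6.27, others 6.05 to 6.10) and antioxidant enzymes (6.21, others 6.00 to 6.03). KO 2 was low for glycolysis (7.09, others 7.20 to 7.21) and KO 4 low for fatty acid oxidation (4.59, others 4.64 to 4.66). WT 4 was low for HIF targets (5.94, others 6.05 to 6.08).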

How the results depend on the processing

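The fits with KO 3 and KO 4 only and with the epithelial markers, the keratocyte markers or Ddx3y alone as covariate were chosen after seeing the data; the other alternatives were planned. Slc4a11 was called under every setting run, with log2 fold changes from -5.38 to -5.22, and the odds ratio for genes near it was 0.80 to 1.35 (Fisher exact p of 0.141 or more). Against 1346 genes higher in KO and 1370 genes lower in KO, an adjusted p under 0.01 gave 450 and 574, and an absolute log2 fold change of at least 1 gave 382 and 213, as stricter thresholds must. The pooled mean of keratocyte, epithelial and pigment markers as covariate gave 578 and 686 genes, with 6 lists higher and 5 lower. The epithelial covariate alone gave 622 and 749, with 6 and 5. KO 3 and KO 4 only gave 527 and 578, with 4 lists higher and 7 lower. Against 11 lists higher and 8 lower, an estimated correlation gave 0 and 0 and fry gave 5 and 5. The epithelial list reversed to medians of -0.18 and -0.019 with the 2 epithelial covariates, which remove it by construction. Leaving out 1 library gave 836 to 1532 genes higher, 965 to 1666 lower, 8 to 12 lists higher and 7 to 9 lower; the lowest counts of genes higher were 836 without WT 3, 850 without WT 5 and 895 without KO 1. The causes of the other changes between fits were not tested.

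Of 101 named genes called besides Slc4a11, 54 were called in the same direction under every setting that tested them. Under the planned settings that kept all libraries the number was 61, and none reversed. A gene that a filter removed was not counted in that fit, such as Inhba, at most 0.93 CPM in any library, with the CPM filter. Over all settings, 253 values of named genes lost their call and 1 gained one, and of the lists 74 lost and 24 gained one. DESeq2 called 1779 genes higher and 1838 lower and limma-voom 1111 and 1280. With the replicate number as a block (replicate block), 750 genes were higher and 941 lower. Same-numbered libraries did not deviate together (correlations of -0.42 to 0.085, none of 5 pairs over 0.1, and 0 of 10 libraries closest to its own number). These correlations run over all tested genes, and uneven epithelial transcripts could hide a weaker link, so they cannot settle whether the numbers pair the samples. The cause of the lower counts with the block was not tested. The Ddx3y level as covariate gave 1234 genes higher and 1320 lower, with 11 and 8 lists. The labels give no time of day or litter, so these could not be adjusted for.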

Other observations

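The count of histone genes and the look at transporter, receptor and sex-linked genes were chosen only after their values were seen, as were the matched random sets for solute carriers. Histone genes were higher in KO in these libraries of polyadenylated RNA, which measure most histone messages less completely. Whether all histone messages changed alike cannot be told from them. Of 27 tested protein-coding genes with symbols starting with Hist, 23 rose, 0 fell and all 27 had a positive log2 fold change, with a median of 1.10. The counts were 23 and 0 alike with TMM, DESeq2 size factors, upper quartile factors and total counts, and 18 of 28 rose with KO 3 and KO 4 only. Their mean log2 CPM was -0.29 to 0.02 in the WT libraries and 0.78 to 1.01 in the KO libraries. Most lie in the clusters on chromosome 13 (20 genes) and chromosome 3 (6 genes), 24 of 27 had a mean under 5 CPM, and near-identical copies make the single genes uncertain. The 2 most abundant of them, Hist1h2bc and Hist1h1c, rose by 0.94 (SE 0.06) and 1.48 (SE 0.14) on the log2 scale.

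Single genes were picked after their values were seen, from no fixed list and without a test of a group. Glrb, the beta subunit of the glycine receptor, fell from 204 ± 11.9 to 80.0 ± 5.01 CPM (SD, n = 5; log2 fold change -1.35, SE 0.06). Of the vesicular monoamine transporters, Slc18a2 had a log2 fold change of -2.21 and Slc18a1 rose by 1.22 (SE 0.11), from 1.15 ± 0.0704 to 2.67 ± 0.143 CPM. The dopamine transporter Slc6a3 had a log2 fold change of -0.56 (SE 0.08), and the vesicle protein Sv2c rose by 2.19.

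Solute carrier genes other than Slc4a11 may be more often changed than other genes in KO, a hypothesis written before its count was seen. Of 246 tested genes named Slc, 66 were called (26.8%), 32 higher and 34 lower, against 17.3% of other protein-coding genes. The odds ratio was 1.75 (95% interval 1.29 to 2.34; Fisher exact p = 2.5e-04). In 10000 random sets matched on mean expression the median was 44 called genes (permutation p = 3.0e-04). The symbol pattern was narrowed, to leave out adaptor genes named after a carrier, once a first count had been seen.

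A fall of LXR targets beside the rise of cholesterol synthesis genes, as low sterol levels could give, was not found. Of 9 tested targets 4 rose (Nr1h3, Abcg4, Srebf1 and Lpcat3) and 0 fell. Those that did not pass went both ways, with Abca1 at -0.46 (edgeR adjusted p = 0.11), Smpdl3a at -0.19, Pltp at -0.05, Mylip at 0.02 and Abcg1 at 0.26. The median log2 fold change was 0.26 (limma camera p = 0.0596 with the preset correlation, in the direction of higher, and p = 0.0860 with an estimated correlation).

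The pools differed in sex makeup. Xist, expressed from the inactive X of females, was at 0.0228 CPM in WT 3, 0.0198 CPM in WT 5 and 0.0211 CPM in KO 2, and at 118 CPM in WT 2. The other 6 libraries lay between 15.2 and 41.5 CPM. The Y-linked gene Ddx3y was found in all 10, from 17.7 CPM in KO 5 to 93.3 CPM in WT 3.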
